A study of Mus musculus with 4 samples.

How the data were processed

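RNA was measured in 4 libraries of basal radial glia isolated from the medial neocortex of mouse embryos at E18.5. Basal radial glia are neural progenitors that keep a basal process and, unlike apical radial glia, have no contact with the ventricle. The labels place all 4 libraries in a single group, so no contrast between groups exists, and they do not say whether the libraries came from separate animals. The p-values below therefore measure only the spread between these samples, which may be technical. The labels name the strain C57BL/6JOlaHsd, a heterozygous Tubb-GFP reporter genotype and the lipophilic dye DiI, but not how reporter and dye were used to isolate the cells.

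Per the labels' protocols, cDNA was made from total RNA with a tailed poly-dT primer and template switching, amplified, sheared and made into Illumina libraries with NEBNext chemistry. Per the submitters' processing notes, reads were demultiplexed with bcl2fastq 2.19.1 and aligned with STAR 2.5.2b to GRCm38. The counter, its strand setting and the annotation release are not given in the sources used here. The deposited counts are whole numbers of reads per Ensembl gene for 45706 genes, and were not normalised. The protocol does not mark strand by its description, so reads from overlapping genes on opposite strands cannot be told apart, and the values of such genes are uncertain. Among the list genes named in the text, the share of exonic bases on the opposite strand from another gene was highest for Hes5 (31.8%), Hopx (27.2%), Ube2c (22.8%), Lhfpl3 (17.6%) and Sfrp2 (16.1%).

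The deposited TPM table holds 15648 of these genes, 15403 of them protein coding. The length behind it was tested from the values. For 8675 of 9107 genes (95.3%), the ratio of deposited count to deposited TPM lay within 0.01 on the log2 scale of a single constant times the whole gene span, introns included. With the merged exons as length this held for 56 genes (0.615%). The counts themselves followed exons: of 395 protein-coding genes lying inside an intron of another gene, 307 had a count and 133 had more counts than their host. Genes with long introns are thus placed low by the deposited TPM, and 6116 of the 21519 protein-coding genes of the count table are outside it, among them Tubb3, Pcna, Rrm2, Notch2, Gja1 and the globins. How its genes were chosen is not given in the sources used here.

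The design had been written for the deposited TPM before its length basis was known. TPM was instead recomputed from the deposited counts with the merged exon length of each gene in GENCODE release M21 (GRCm38), in which 45143 of the 45706 identifiers matched; the other 563 held between 0.120% and 0.125% of the counts. This exon-length TPM is the TPM of the text unless the deposited TPM is named. The fit as first designed, on the deposited scale, was kept as an alternative chosen after seeing the data, as were the longest transcript as length and the exon scale restricted to the genes of the deposited TPM table. On the deposited scale, 9640 genes lay above and 2859 below 1 TPM among 13822 tested, against 10699 and 1469 by exon length for the same genes, and 762 genes called above 1 TPM by exon length were called below it on the deposited scale.

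Each gene with at least 10 counts in total was tested against a level of 1 TPM with a one-sample quasi-likelihood F test in edgeR 4.0.16 (R 4.3.3), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The offset of each gene and library was the log of the count expected at 1 TPM. Fixed lists of genes (29 lists with 308 matched genes, 5 of them in more than one list) were summarised as the median over members of log2(TPM + 1) in each library, and the mean median was ranked among the medians of 10000 random lists of the same size. Random lists were drawn from all 20991 genes with at least 10 counts, 15401 of them protein coding. Of the protein-coding genes 11659 lay above 1 TPM, against 13809 of all, so percentiles among protein-coding genes alone may be lower. Differences between 22 pairs of lists were tested with an exact two-sided sign-flip permutation test, whose smallest p with 4 libraries is 0.125. Differences between 26 pairs of genes were tested on log2((TPM + 1)/(TPM + 1)) with limma 3.58.1, which shares the estimate of the spread over the pairs. A test for genes more variable than others of like abundance compared the residual quasi-dispersion with its trend in edgeR, for genes with at least 40 counts. No test of overlap between variable genes and lists was made, since no gene was called. The groups, lists, pairs, tests and all other alternative settings were fixed before the data were examined.

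The genes named were chosen by rule: in each list the 4 members of highest mean TPM among those called above 1 TPM; always Hopx, Pax6, Sox2, Eomes, Prom1, Tubb3, Gfap and Mki67; the gene pairs; and the 10 genes of highest TPM. Some genes and pairs this rule takes are not reported here, though they stay in the counts, medians and tests of their lists. Other genes named were chosen after their values were seen. The settings fixed beforehand covered TMM and DESeq2 size factors, a DESeq2 1.42.0 Wald test, limma on log2(TPM + 0.1), filters of 1, 40 and 400 counts, reference levels of 0.5 and 5 TPM, another pseudocount, counts per 1e+06 reads (CPM), the mean in place of the median, list members with at least 10 counts only, TMM without mitochondrial genes, a prior fitted without robustness, and leaving out each library. A list gene, Ahsp, had no match in the annotation, and Pals1 was matched through a synonym.

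The level test was tested on simulated data of 20991 genes. edgeR called 45 of 50 genes set at 2 TPM and 46 of 50 set at 4 TPM above 1 TPM, and 29 of 50 set at 0.5 TPM and 46 of 50 set at 0.25 TPM below it. A single gene of 50 set at exactly 1 TPM was called. In the variability test, simulated over 16703 genes, 73 of 100 genes with 16 times the trended dispersion were called, against 15 of 100 with 4 times, and 12 of all 100 calls were false. DESeq2 dispersion outliers held more of the simulated genes, 83 and 31 of 100, but 98 of 212 calls were false. Every other simulated gene had exactly the trended dispersion, without scatter around it. The shares found in these simulations may therefore be higher than in the real data. Totals of 26540656 to 34837657 counts per library put 1 read per kilobase of exon at 0.0888 to 0.121 TPM, and a count of 0 allows up to 3 counts, or 0.0861 to 0.113 CPM. Amplified reads without molecular identifiers are not independent molecules, so these limits cover counting error only. Tables were handled with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and figures drawn with matplotlib 3.10.9.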

Results

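The series profiled the transcriptome of basal radial glia isolated from the medial neocortex of mouse embryos at E18.5, in 4 replicate libraries. Its title ties these cells to Hopx, a homeodomain-only protein known as a marker of basal radial glia in the human neocortex. The question the data can answer is which genes these libraries held, and at what level relative to each other. Library totals were 27979873, 34837657, 29824888 and 26540656 counts for replicates 1 to 4, with between 23128 and 23900 genes having a count. Mitochondrial genes took 1.32% to 1.51% of the counts and protein-coding genes 97.1% to 97.5%. Of 20991 genes tested by edgeR's quasi-likelihood test, 13809 lay above 1 TPM and 2447 below it. Among the 15401 protein-coding genes these numbers were 11659 and 1729. Of the 308 fixed list genes, 223 were above 1 TPM. Since most tested genes lay above 1 TPM, a list is not set apart by having most of its members above it.

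Radial glial genes were present throughout. All 18 members of the radial glia list were above 1 TPM, and the list's median was 5.002 ± 0.24 on the log2(TPM + 1) scale (SD, n = 4), or 31.0 TPM, at percentile 99.8 of random lists. Its most abundant members were Fabp7, the brain lipid-binding protein, at 4631 ± 382 TPM (SD, n = 4), Dbi, an acyl-CoA binding protein, at 944 ± 95.3 TPM, Mfge8 at 500.2 ± 48.4 TPM, and Slc1a3, the glutamate transporter GLAST, at 267 ± 20.5 TPM. The progenitor transcription factors were lower, with Sox2 at 30.1 ± 4.10 TPM and Pax6 at 21.1 ± 2.40 TPM. Adjusted over the list alone, the number of members above 1 TPM was the same as over all genes for 28 of the 29 lists, and the exception is given with its list.

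Of the 12 members of the basal radial glia list, 11 were above 1 TPM, with a median of 3.05 ± 0.16 (log2, SD, n = 4), or 7.28 TPM, at percentile 70.1. The highest were Tnc, the matrix glycoprotein tenascin C, at 264 ± 38.4 TPM, Pdpn, the membrane glycoprotein podoplanin, at 157 ± 30.5 TPM, Ptprz1, a receptor tyrosine phosphatase, at 104 ± 8.59 TPM, and the fatty acid enzyme Acsbg1 at 64.9 ± 4.85 TPM. Hopx itself (ENSMUSG00000059325; GRCm38 chromosome 5, 77086988 to 77115121) ranked 10 of the 12, at 3.03 ± 0.41 TPM (SD, n = 4). Its counts were 35, 55, 51 and 35, and the exact Poisson 95% intervals of the libraries together spanned 1.80 to 4.60 TPM. It lay above 1 TPM by 1.58 ± 0.21 on the log2 scale (SE; edgeR adjusted p = 1.96e-05). In the same libraries, 3 of 16 genes specific to other organs, Acta1 (7.48 TPM), Gcg (5.16 TPM) and Pnlip (4.38 TPM), were at a higher level than Hopx. Of these, the Acta1 value is uncertain, since its reads resemble those of Actb. The median of the 16 genes was 0.0235 TPM, below Hopx. The Hopx value is uncertain because the antisense gene Hopxos shares 412 of the 1516 exonic bases of Hopx (27.2%). On the deposited scale, which divides by the gene span of 28134 bases, Hopx was at 0.573 ± 0.0795 TPM and called below 1 TPM, and 7 of the 12 list members were above it.

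Genes of the apical junction and polarity machinery had a higher median than the basal radial glia list by exon length. On the deposited scale the basal minus apical difference was -0.027 ± 0.23 (log2, SD, n = 4), within the spread between libraries. Of the 14 members, 12 were above and 1 below 1 TPM, with a median of 3.99 ± 0.17 (log2, SD, n = 4), or 14.9 TPM. Cdc42 was at 987 ± 61.4 TPM, Ctnnb1, beta-catenin, at 140.3 ± 9.77 TPM, Cdh2, N-cadherin, at 51.4 ± 3.98 TPM and Llgl1 at 41.9 ± 6.09 TPM. These 4 genes are used by many cell types. Prom1, which encodes the apical membrane protein prominin-1, was at 20.2 ± 4.35 TPM. Crb2 and Crb1, members of the apical Crumbs complex, were at 1.096 ± 0.45 TPM (edgeR adjusted p = 0.619 against 1 TPM) and 0.307 ± 0.0727 TPM (edgeR adjusted p = 0.000202, below it).

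**Figure D1:**
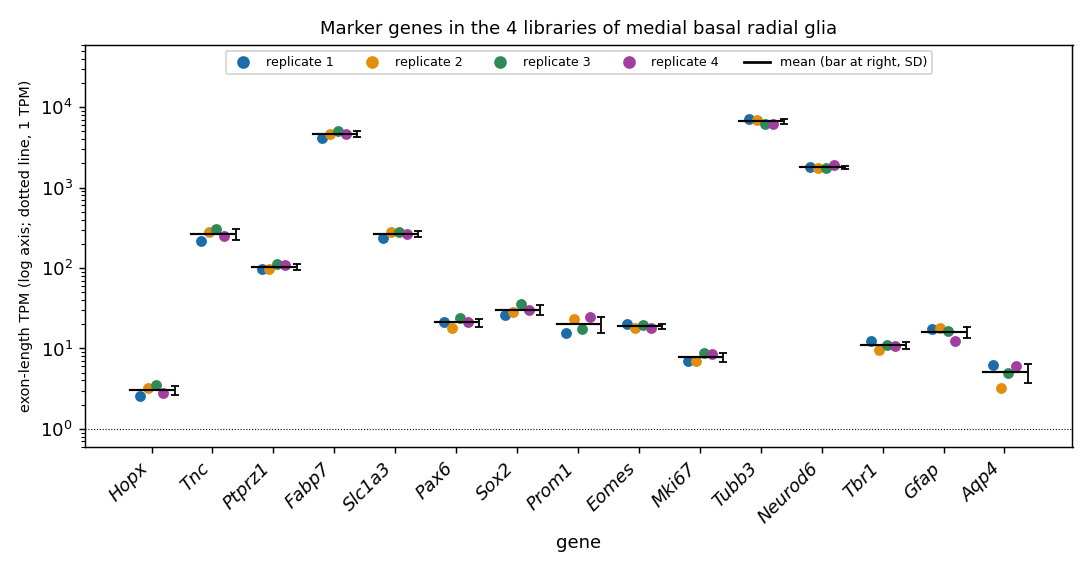
Exon-length TPM (log axis) of 15 marker genes in each of the 4 libraries (coloured points), with the mean as a line and the SD as a bar at its right; the dotted line marks 1 TPM. Tubb3 lay at 6691 TPM and Fabp7 at 4631 TPM, while Hopx lay at 3.03 TPM.

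Intermediate progenitor genes were abundant too, and which of the 2 lists was higher depended on the length scale and summary used. Of 10 members, 9 were above 1 TPM, and the median was 5.27 ± 0.25 (log2, SD, n = 4), or 37.6 TPM. Gadd45g was at 511 ± 64.1 TPM, the antiproliferative gene Btg2 at 425 ± 21.8 TPM, the somatostatin receptor Sstr2 at 254 ± 25 TPM and Mfng at 119 ± 4.66 TPM. Eomes, the transcription factor Tbr2 that marks these progenitors, was at 18.9 ± 1.24 TPM (SD, n = 4). The radial glia median minus the intermediate progenitor median was -0.27 ± 0.34 on the log2 scale (SD, n = 4; exact sign-flip permutation p = 0.25, adjusted 0.25), with radial glia higher in 1 of 4 libraries. That difference was within the spread between libraries, and its sign turned with the mean of members (0.54 ± 0.18), on counts per 1e+06 reads (CPM; 0.96 ± 0.17) and with the longest transcript as length (0.29 ± 0.28).

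Neuronal transcripts stood above the progenitor lists. All 14 members of the neuron list were above 1 TPM, with a median of 7.31 ± 0.12 (log2, SD, n = 4), or 158 TPM. Tubb3, the neuronal beta-tubulin, was at 6691 ± 496 TPM, the cortical neuron transcription factor Neurod6 at 1791 ± 70.3 TPM, the growth cone protein Gap43 at 662 ± 38.9 TPM and Stmn2 at 449 ± 23.6 TPM. The radial glia median lay below the neuron median by -2.31 ± 0.31 (log2 difference, SD, n = 4), and the intermediate progenitor median by -2.04 ± 0.35, both in all 4 libraries (exact sign-flip permutation p = 0.13, the smallest possible; adjusted 0.131). The first difference shrank on the deposited scale, where neuron minus radial glia was 0.475 ± 0.0907, and the second was 0.16 ± 0.19 there, in the other direction but within the spread between libraries.

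All 7 deep-layer and all 7 upper-layer neuron genes were above 1 TPM. Upper-layer genes were the more abundant, with a median of 6.08 ± 0.064 (log2, SD, n = 4), or 66.5 TPM, against 3.60 ± 0.13, or 11.1 TPM, for deep-layer genes. The POU-domain transcription factors Pou3f2 and Pou3f3 were at 415 ± 53.0 and 177 ± 17.5 TPM and Mef2c at 64.0 ± 6.76 TPM. Among deep-layer genes, Fezf2, a determinant of subcerebral neurons, was at 26.2 ± 2.15 TPM, Tle4 at 14.7 ± 1.66 TPM, Sox5 at 14.1 ± 0.797 TPM and Tbr1 at 11.05 ± 1.14 TPM. Deep minus upper was -2.48 ± 0.13 (log2, SD, n = 4) and negative in all 4 libraries (exact permutation p = 0.13, adjusted 0.131). The libraries do not show which cells held these transcripts, so this difference does not measure upper-layer against deep-layer neurons. Of the interneuron list, 8 of 11 were above and 2 below 1 TPM (9 above when adjusted over the list alone), and the median was 2.24 ± 0.18, or 3.72 TPM. The neuropeptide genes Npy and Sst were at 157 ± 37.2 and 77.1 ± 24.6 TPM, Sp8 at 43.5 ± 11.2 TPM and Dlx5 at 5.76 ± 2.01 TPM.

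Macroglial genes were detected as a group. All 11 astrocyte genes were above 1 TPM, with a median of 4.08 ± 0.24 (log2, SD, n = 4), or 15.9 TPM. Aldoc was at 552 ± 56.1 TPM, Id3 at 291 ± 48.3 TPM, Sparcl1 at 219.5 ± 16.8 TPM and Clu at 170.1 ± 26.2 TPM, and the intermediate filament gene Gfap at 16.1 ± 2.59 TPM. All 9 oligodendrocyte lineage genes were above 1 TPM, with a median of 3.59 ± 0.14. Olig1 was at 16.4 ± 1.62 TPM, Pdgfra, the receptor that marks oligodendrocyte precursors, at 14.4 ± 1.19 TPM and Lhfpl3 at 13.8 ± 2.63 TPM. The radial glia median exceeded the astrocyte median by 0.92 ± 0.26 and the oligodendrocyte lineage median by 1.42 ± 0.32 (log2, SD, n = 4), in all 4 libraries (exact permutation p = 0.13, adjusted 0.131). The basal radial glia median minus the astrocyte median was -1.03 ± 0.10, and minus the apical and intermediate progenitor medians -0.94 ± 0.094 and -2.22 ± 0.17, each negative in all 4 libraries with the same p. Lhfpl3 (0.293 TPM) and Sox5 (0.745 TPM) were called below 1 TPM on the deposited scale.

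Most lists of other cell types had few members above 1 TPM, with the microglia and erythroid lists as exceptions. The source of these transcripts was not tested. Of the ependymal list 1 of 9 was above 1 TPM (Mcidas, 1.81 ± 0.332 TPM; not called with the longest transcript, edgeR adjusted p = 0.0776), of the Cajal-Retzius list 2 of 9 (Calb2, 49.8 ± 6.65 TPM, and Nhlh2, 1.74 ± 0.466 TPM), and of the choroid plexus list 1 of 9 (Ttr, transthyretin, 67.8 ± 12.5 TPM). The endothelium list had 2 of 9 above (Esam, 1.95 ± 0.865 TPM, and Egfl7, 1.71 ± 0.621 TPM), the mural cell list 2 of 6 (Pdgfrb, 6.38 ± 1.96 TPM, and Rgs5, 2.39 ± 0.642 TPM) and the meningeal list 2 of 10 (Crabp2, 2.79 ± 0.933 TPM, and Lum, 1.98 ± 0.231 TPM). The endothelial count was 0 without replicate 1 and 1 without replicate 2. Their medians were 0.23 ± 0.17, 0.42 ± 0.13, 0.20 ± 0.12, 0.37 ± 0.067, 0.77 ± 0.38 and 0.64 ± 0.093 in that order (log2, SD, n = 4). Of 12 microglia genes, 7 were above 1 TPM, with a median of 1.76 ± 0.48. The microglia count ran from 6 to 9 when each library was left out. C1qb was at 13.3 ± 4.29 TPM, Tyrobp at 5.28 ± 2.41 TPM and P2ry12 at 5.15 ± 2.2 TPM.

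Of the 7 erythroid genes matched, 6 were above 1 TPM, with a median of 8.57 ± 0.55 (log2, SD, n = 4), or 379 TPM. The globin genes Hbb-bs, Hba-a1, Hba-a2 and Hbb-bt were at 1183 ± 357, 719 ± 207, 587 ± 157 and 400.04 ± 155 TPM. Reads of the near-identical globin copies can be split among them, so single values are uncertain. All 7 erythroid members were highest in replicate 2, and 10 of the 12 microglia members were lowest in replicate 4. The radial glia median was -3.57 ± 0.44 against the erythroid median (log2 difference, SD, n = 4), and 4.82 on the deposited scale, whose table holds 3 of the 7 genes and none of the globins. In further fixed pairs the radial glia median was higher in all 4 libraries, by 2.76 ± 0.42 (interneuron), 4.77 ± 0.33 (ependymal), 4.58 ± 0.37 (Cajal-Retzius), 3.25 ± 0.38 (microglia), 4.63 ± 0.27 (endothelium), 4.36 ± 0.28 (meninges) and 4.80 ± 0.18 (choroid plexus). Each of these tests, the erythroid one included, gave the smallest possible exact permutation p of 0.13 (adjusted 0.131).

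**Figure D2:**
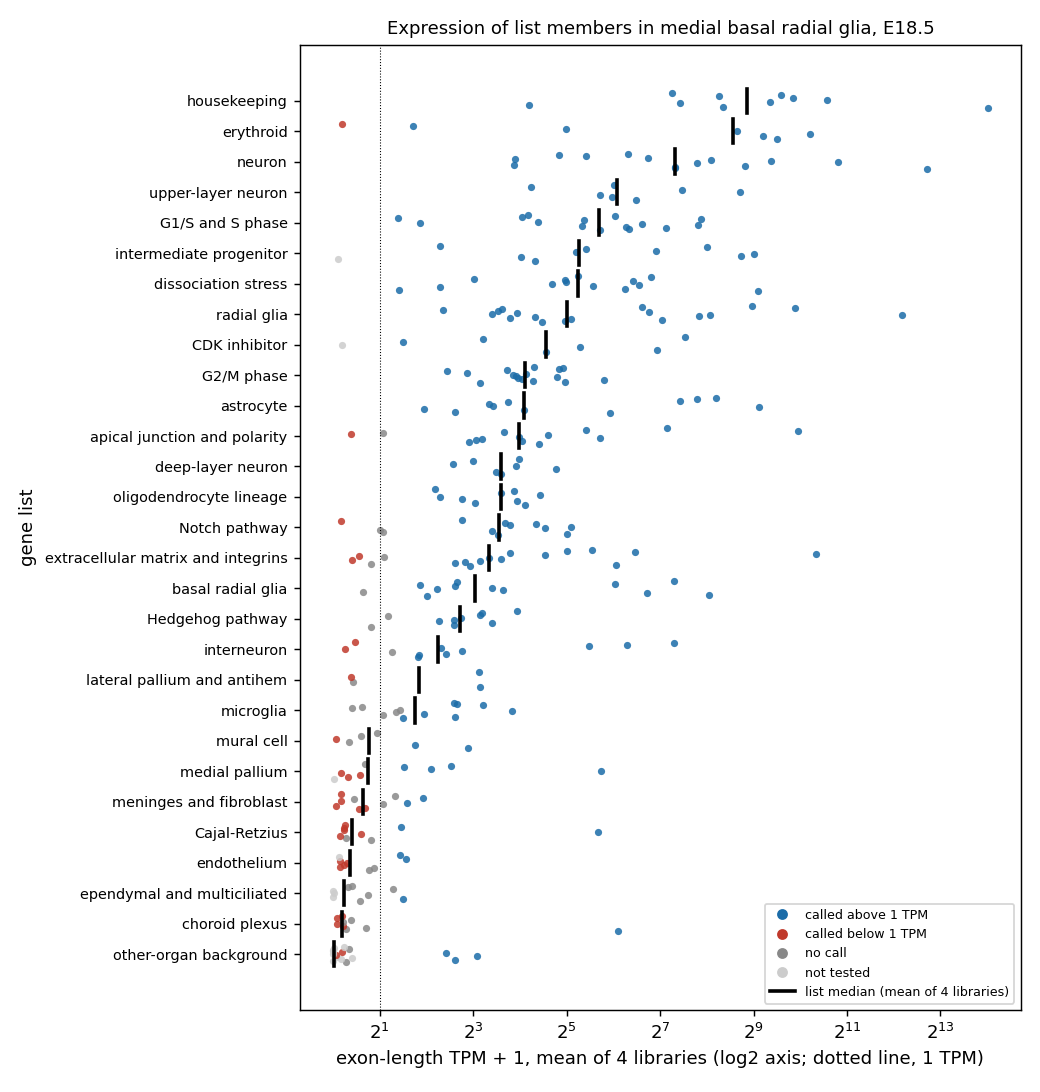
Mean exon-length TPM + 1 over the 4 libraries (log2 axis) of each member of the 29 fixed gene lists (points, coloured by the call against 1 TPM), with the list median as a black line; the dotted line marks 1 TPM. The neuron median lay at 158 TPM, the radial glia median at 31.0 TPM and the basal radial glia median at 7.28 TPM.

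Of the 2 lists of genes with a known regional expression in the pallium, neither had most of its members called above 1 TPM. Of 9 medial pallium genes, 4 were above and 3 below 1 TPM, with a median of 0.75 ± 0.20 (log2, SD, n = 4). Zbtb20, a transcription factor of the hippocampal primordium, was at 52.5 ± 4.18 TPM, Dmrta2 at 4.74 ± 1.49 TPM, Prox1 at 3.27 ± 0.567 TPM and Lef1 at 1.89 ± 0.516 TPM. Of 4 lateral pallium genes, 2 were above 1 TPM, Sfrp2 at 7.81 ± 1.14 TPM and Tgfa at 7.75 ± 0.505 TPM, and the median was 1.84 ± 0.18. Medial minus lateral was -1.08 ± 0.091 (log2, SD, n = 4), negative in all 4 libraries (exact permutation p = 0.13, adjusted 0.131). Lef1 was called below 1 TPM on the deposited scale, at 0.512 TPM.

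Cell cycle genes were expressed as a group, together with their inhibitors. All 15 members of the S phase list were above 1 TPM, with a median of 5.70 ± 0.11 (log2, SD, n = 4), or 51.1 TPM. Rrm2, a subunit of ribonucleotide reductase, was at 233 ± 23.6 TPM, the replicative helicase genes Mcm7 and Mcm4 at 224 ± 5.61 and 139 ± 19.6 TPM, and Pcna at 96.7 ± 8.39 TPM. All 16 G2/M genes were above 1 TPM, with a median of 4.10 ± 0.11, or 16.1 TPM. Ccnb2 was at 54.7 ± 6.63 TPM, Top2a at 30.2 ± 4.46 TPM, Tpx2 at 29.1 ± 3.50 TPM, Ube2c at 27.8 ± 5.40 TPM and Mki67, the proliferation marker Ki-67, at 7.85 ± 0.998 TPM. Of 7 CDK inhibitor genes, 6 were above 1 TPM, with a median of 4.55 ± 0.075, or 22.4 TPM. Cdkn2d was at 183 ± 5.45 TPM, Cdkn1b at 121 ± 4.4 TPM, Cdkn1c at 38.2 ± 2.91 TPM and Cdkn1a at 22.5 ± 1.22 TPM. S phase minus G2/M was 1.60 ± 0.13 and G2/M minus CDK inhibitor -0.45 ± 0.18 (log2, SD, n = 4), each of a single sign in all 4 libraries (exact permutation p = 0.13, adjusted 0.131).

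Of 12 Notch pathway genes, 9 were above and 1 below 1 TPM, with a median of 3.55 ± 0.10 (log2, SD, n = 4), or 10.7 TPM. Hes1, a transcriptional effector of Notch, was at 32.9 ± 8.28 TPM, Notch2 at 31.2 ± 4.18 TPM, the ligand gene Jag1 at 22.1 ± 3.65 TPM and Hey1 at 19.2 ± 7.86 TPM. Of 10 Hedgehog pathway genes, 8 were above 1 TPM, with a median of 2.72 ± 0.080, or 5.61 TPM. The co-receptor genes Gas1, Cdon and Boc were at 14.4 ± 2.29, 8.13 ± 1.63 and 7.82 ± 1.04 TPM and Gli3 at 9.57 ± 2.36 TPM, while the pathway target Gli1 was at 0.766 ± 0.372 TPM (edgeR adjusted p = 0.273 against 1 TPM). Of 17 extracellular matrix and integrin genes, 13 were above and 2 below 1 TPM, with a median of 3.33 ± 0.24, or 9.05 TPM. The proteoglycan gene Ncan reached 1294 ± 85.4 TPM, Sparc 87.6 ± 12.2 TPM, Itgb1 65.5 ± 5.44 TPM and Sdc4 46.0 ± 8.11 TPM.

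All 13 genes of the dissociation stress list were above 1 TPM, with a median of 5.25 ± 0.066 (log2, SD, n = 4), or 36.9 TPM. The immediate early genes Fos, Nr4a1, Egr1 and Atf3 were at 546 ± 13.9, 111 ± 3.54, 92.1 ± 13.8 and 84.6 ± 3.04 TPM. Cells of the embryonic cortex also express several of these genes without dissociation. All 10 housekeeping genes were above 1 TPM, with a median of 8.86 ± 0.024, or 464 TPM; Actb was at 16511 ± 454 TPM, Rpl13a at 1530.1 ± 107 TPM and Ywhaz at 920.5 ± 43.3 TPM. Of 16 genes specific to other organs, 3 were above 1 TPM and the median was 0.033 ± 0.025. These 3 were the muscle actin Acta1 (7.48 ± 1.89 TPM; uncertain, since its reads resemble those of Actb), the proglucagon gene Gcg (5.16 ± 1.12 TPM) and the pancreatic lipase gene Pnlip (4.38 ± 0.828 TPM). No count was found for 4 of the 16, Ins2, Umod, Ambp and Fabp2, which allows up to 0.113 CPM in the shallowest library. The radial glia and neuron medians exceeded this background by 4.97 ± 0.24 and 7.28 ± 0.11 (log2, SD, n = 4; exact permutation p = 0.13, adjusted 0.131, in all 4 libraries).

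Within libraries, 23 of 26 fixed gene pairs differed by limma's one-sample test. Hopx was below Eomes, with a log2 ratio of -2.31 ± 0.11 (SE, n = 4; limma adjusted p = 1.93e-08), below Prom1 (-2.38 ± 0.13, adjusted p = 6.43e-08) and below Tnc (-6.04 ± 0.095, adjusted p = 9.96e-12). Tnc and Ptprz1 exceeded Prom1 by 3.66 and 2.34, and Sox2 exceeded Eomes by 0.64. No difference was called between Pax6 and Eomes (0.15 ± 0.10; limma adjusted p = 0.175), Hes5 and Neurog2 (-0.25 ± 0.14; adjusted p = 0.124) or Nes and Gfap (0.25 ± 0.11; adjusted p = 0.0644). The Hes5 difference was called without replicate 2 (-0.33, limma adjusted p = 0.0402) and without replicate 3 (-0.37, limma adjusted p = 0.0245). In each of those fits Hes5 was higher in 1 of 3 libraries, with SDs of 0.404 and 0.336. Both calls rest largely on the spread shared over the 26 pairs, not on that of this pair. All 3 uncalled pairs were called when no length correction was made. By CPM limma called Pax6/Eomes at 1.61 (adjusted p = 2.62e-08), Hes5/Neurog2 at -0.86 (adjusted p = 8.22e-05) and Nes/Gfap at 0.84 (adjusted p = 2.94e-05). With the longest transcript, Pax6/Eomes was called at 1.28 (limma adjusted p = 6.84e-07) and Nes/Gfap in the other direction, at -0.32 (limma adjusted p = 0.0208). Nes/Gfap was called on the deposited scale at 1.35 (limma adjusted p = 2.41e-10) and Pax6/Eomes was -0.19 (limma adjusted p = 0.142). Hes5/Neurog2 stayed uncalled with the longest transcript (-0.15, limma adjusted p = 0.305) and on the deposited scale (-0.19, limma adjusted p = 0.201). Sox2, Pax6 and Vim lay below Tubb3, with log2 ratios of -7.75, -8.25 and -4.89, while Fabp7 lay above the neuronal gene Dcx by 4.85. Cyclin D2 exceeded cyclin D1 (Ccnd2/Ccnd1 4.48), and Mki67 lay below Cdkn1b (-3.79). Other called log2 ratios were 5.48 for Slc1a3/Aqp4, 1.04 for Hes1/Neurog2, 4.02 for Sox9/Olig2, 5.03 for Aldoc/Gfap, 0.73 for Eomes/Tbr1, 2.79 for Emx1/Gad2, 2.58 for Gli3/Gli1, 1.48 for Notch2/Notch1 and 2.60 for Gja1/Cldn5. All these ratios hold a pseudocount of 1 TPM, which shrinks those of genes near or below that level. With a pseudocount of 0.1, Gli3/Gli1 was 3.55 and Gja1/Cldn5 3.67, and all 26 pairs kept their sign and call. On the deposited scale Gli3/Gli1 was 0.090 (limma adjusted p = 0.507). By CPM, Sox2/Eomes was called in the other direction, at -0.33 (limma adjusted p = 0.0152).

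**Figure D3:**
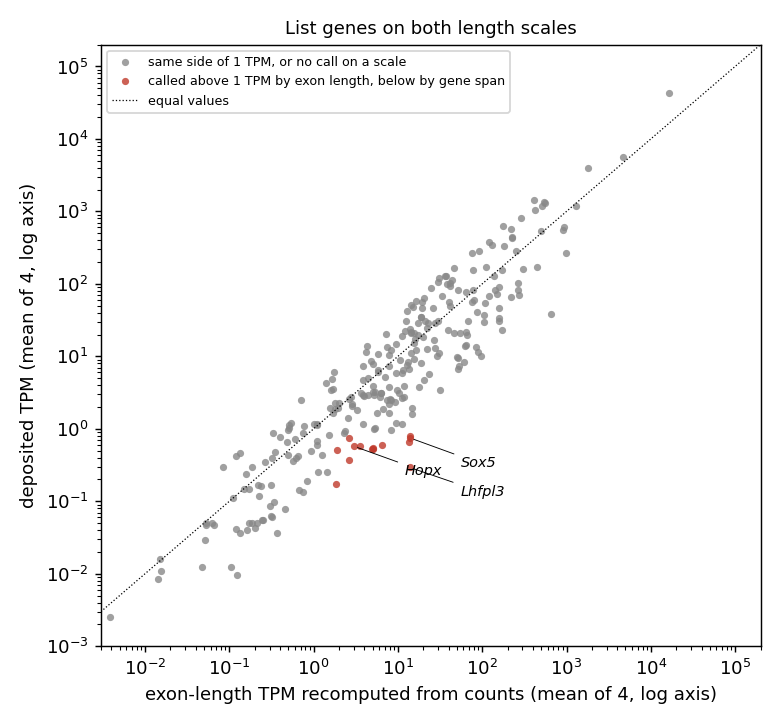
Deposited TPM against exon-length TPM (log axes, means of 4 libraries) for the 281 list genes with a value above 0 on both scales; the dotted line marks equal values. The 14 red points, Hopx, Sox5 and Lhfpl3 among them, were called above 1 TPM by exon length and below it on the deposited scale.

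The 10 most abundant transcripts included tubulin, actin and mitochondrial genes. Tuba1a, an alpha-tubulin of postmitotic neurons, was at 17314 ± 437 TPM, followed by Actb, mt-Cytb (12322 ± 1003 TPM), the actin-sequestering gene Tmsb4x (9425 ± 497 TPM), the transcription factor Sox11 (8283 ± 1394 TPM), mt-Rnr2 (7589.8 ± 767 TPM), Dpysl2 (6721 ± 865 TPM) and Tubb3. The short genes Mir6236 (123 bases, 35677 ± 1942 TPM) and Gm23935 (57 bases, 8479 ± 354 TPM) also ranked among the 10 highest. Their length is below that of a typical fragment, so their TPM is uncertain.

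The 4 libraries resembled each other closely. Pearson correlations across genes of log2(TPM + 1) ran from 0.986 to 0.989 over the 6 library pairs, and Spearman correlations from 0.916 to 0.921; genes are not independent replicates. No library was a copy of another, since the chi-square per degree of freedom of their counts ran from 9.21 to 23.9, and the 3 highest values all involved replicate 4. Of 16706 genes with at least 40 counts, edgeR called 0 more variable than the trend, with 793 at an unadjusted p under 0.05. DESeq2 marked 258 as dispersion outliers and limma-voom called 2. The common biological coefficient of variation was 18.7%. The linker histone gene Hist1h1c and the ribosomal protein gene Rpl13 had the highest ratios of variance to trend, 67.3 and 60.9 (edgeR adjusted p = 0.0791 for both). Among the 10 most abundant genes, Sox11 and Dpysl2 had the highest, 8.78 and 5.06 (edgeR adjusted p = 0.97 for both). Even the ratios of Hist1h1c and Rpl13 were not enough for a call, so 0 calls do not show equal variability.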

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

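All tests in this part were chosen after replicate 4 had been seen to differ; those of transcript length and GC content were written down before their correlations were computed, and the tests after GC and length correction once they were known. Of 197 values checked over the 4 libraries, 12 (6.09%) had a library far from the other 3 by Dixon's test, and chance alone would give about 5%. Replicate 4 was the library set apart in 6 of the 12, replicate 2 in 4, replicate 1 in 2 and replicate 3 in 0.

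In replicate 4, Sox11 was at 10370 TPM against 7507 to 7628 TPM in the others, Actb at 17190 TPM against 16230 to 16360 TPM, and the N-cadherin gene Cdh2 at 45.5 TPM against 52.8 to 54.0 TPM. The 10 most abundant genes took 8.98% of its counts, against 8.14% to 8.25%. Its basal radial glia median was 2.82 on the log2(TPM + 1) scale against 3.10 to 3.16, and its mural cell median 1.34 against 0.54 to 0.63. In replicate 2, the globin genes stood apart: Hbb-bs was at 1712 TPM against 932 to 1060.1 TPM, Hba-a1 at 1027 TPM against 579 to 637 TPM, and Hba-a2 at 820.6 TPM against 475 to 527 TPM. The lateral pallium median of replicate 2 was 2.11, against 1.74 to 1.75. In replicate 1, Btg2 was at 392.4 TPM against 433 to 439 TPM, and the basal radial glia median minus the intermediate progenitor median was -2.47 against -2.17 to -2.11.

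Replicate 4 deviated most from the rest over 11374 genes with at least 400 counts, with an SD across genes of 0.304 on the log2 scale against 0.23 to 0.261. Transcript length stays open as a partial source: its Spearman correlation across genes was 0.244 in replicate 4 and -0.264 in replicate 2, and although a larger size in another replicate had been set as the bar against it, an opposite sign there decides nothing, since each deviation is taken from the other libraries. GC content stays open as a partial source, since the correlation with transcript GC content was -0.512 in replicate 4, against 0.298, 0.288 and 0.0555 in replicates 1 to 3, which is consistent with a technical difference in amplification or sequencing. Replicate 4 still had the highest SD with the GC trend removed from every library, 0.269 against 0.252 for the next (gap 0.017, bootstrap SD over genes 0.0033). With the length trend removed it was 0.297 against 0.254 (gap 0.043, bootstrap SD 0.0035). This does not exclude either as the whole source. Medians over bins of genes may remove a trend incompletely, and the bootstrap treats genes as independent. Replicate 4 also had the fewest counts (26540656), which adds counting noise. Yet replicate 1 had 27979873 counts and an uncorrected SD of 0.24. The deepest library, replicate 2 (34837657 counts), had an SD of 0.261, the highest after replicate 4. The SDs thus did not follow depth, which argues against depth as the main source. Sox11 kept a deviation of 0.33 of its 0.45 after the GC correction, and no biological explanation was tested, since the design has a single group.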

How the results depend on the processing

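The alternatives on the deposited scale, with the longest transcript and on the genes of the deposited TPM table alone were chosen after the data were seen; all others were planned. Of 2618 values recomputed under an alternative, 27 reversed, 9 lost a call, 7 gained one, 131 moved by more than the spread between libraries or 1.5 times a count, and 2444 had none of these labels. Moves in size were checked only for counts, list levels and library correlations. List differences were checked for sign alone, and gene pairs and gene levels for sign and call. A value among the 2444 can therefore differ in size, as neuron minus radial glia did (2.31 by exon length, 0.475 on the deposited scale). The number of genes above 1 TPM stayed within 1.5 times 13809 under every alternative, from 9513 against 5 TPM to 15523 against 0.5 TPM. The number below moved from 2447 to 3755 with limma on log2(TPM + 0.1), 6631 with at least 1 count, 967 with at least 40 counts, 684 against 0.5 TPM, 9296 against 5 TPM, 1469 among the genes of the deposited TPM table, and 1446 to 1612 when each replicate was left out; filters and fewer genes or libraries change what can be called, and the other causes were not tested. Genes more variable than the trend numbered 0, but 11 with at least 400 counts, 258 by DESeq2, 2 by limma-voom and 0 to 3 when each replicate was left out; the cause was not tested. The lowest library correlation, 0.986, became 0.983 over genes with at least 10 counts and 0.965 with a pseudocount of 0.1, by giving low genes more or less weight.

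The radial glia minus intermediate progenitor difference (-0.27) turned to 0.54 with the mean of members, 0.96 by CPM and 0.29 with the longest transcript; the cause was not tested. On the deposited scale, radial glia minus erythroid became 4.82, since the globins are outside that table, and intermediate progenitor minus neuron 0.16. Gene pairs that turned were Sox2/Eomes by CPM (-0.33; limma adjusted p = 0.0152), Pax6/Eomes on the deposited scale (-0.19), a pair not named here on the same scale (0.69), and Nes/Gfap with the longest transcript (-0.32; limma adjusted p = 0.0208), all but Pax6/Eomes called in the other direction. Genes above 1 TPM by exon length lay below it on the deposited scale, through their gene span, for Sox5 (-0.42), Lhfpl3 (-1.77), Lef1 (-0.97) and Hopx (-0.80 on the log2 scale); P2ry12 (-0.017; edgeR adjusted p = 0.947) and Rgs5 (-0.080; 0.699) were not told apart from 1 TPM there. Against a level of 5 TPM, which by construction lies above them, the log2 values were -1.46 for Mcidas, -1.53 for Nhlh2, -1.36 for Esam, -1.54 for Egfl7, -1.07 for Rgs5, -0.84 for Crabp2, -1.34 for Lum, -0.077 for Dmrta2, -0.62 for Prox1, -1.41 for Lef1, -0.19 for Pnlip and -0.72 for Hopx. Without replicate 1, Esam (edgeR adjusted p = 0.0565) and Egfl7 (0.0736) lost their calls, as did Egfl7 without replicate 2 (0.0545), Mcidas with the longest transcript (0.0776), and Dlx5 (0.35), Tyrobp (0.777), P2ry12 (0.853) and Gcg (0.816) against 5 TPM, and the pair Gli3/Gli1 on the deposited scale. Calls gained were those of Pax6/Eomes, Hes5/Neurog2 and Nes/Gfap by CPM (1.61, -0.86 and 0.84), of Pax6/Eomes with the longest transcript (1.28), of Nes/Gfap on the deposited scale (1.35), and of Hes5/Neurog2 without replicate 2 (-0.33) and without replicate 3 (-0.37). The Hes5/Neurog2 calls without a replicate rested largely on the spread shared over pairs, with Hes5 higher in 1 of 3 libraries each time. At this depth a count of 0 allows up to 0.0861 to 0.113 CPM; other depths were not tested. No paired analysis was possible because the labels give a single group.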

Other observations

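All tests in this part were chosen after the results were seen, except the difference between the neuron and radial glia lists and its value by CPM, which were fixed before. Several gene groups had most of their extremes in the same library. In replicate 3, 13 of the 18 radial glia genes and 7 of the 12 basal radial glia genes had their highest TPM, whereas 8 of the 10 intermediate progenitor genes were highest in replicate 1. In replicate 4, 6 of the 7 upper-layer neuron genes and 9 of the 16 G2/M genes were highest, and 10 of the 12 microglia genes were lowest. Hes6, an intermediate progenitor gene, ran from 23.8 TPM in replicate 4 to 56.5 TPM in replicate 1. With genes of a list correlated and the libraries unordered, these counts carry no p-value.

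Transcripts of both sex chromosomes' marker genes were present in each library. Xist, the RNA that coats the inactive X chromosome, was at 10.2 ± 2.15 TPM (SD, n = 4), with 1579, 1535, 2209 and 1561 counts. The Y-linked genes Ddx3y, Eif2s3y, Uty and Kdm5d were in every library too, at 19.8 ± 3.09, 15.0 ± 2.56, 2.81 ± 0.41 and 1.86 ± 0.304 TPM.

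Neuronal genes lay above radial glial genes in libraries labelled as radial glia, by 2.31 ± 0.31 on the log2 scale (SD, n = 4). The length scale did not account for all of it. The difference was 2.14 ± 0.16 by CPM, 2.12 ± 0.21 with the longest transcript and 0.475 ± 0.0907 on the deposited scale, the smallest of the 4. Most of the difference was gone on the deposited scale, so much of its size depended on the length scale. The deposited scale covers all 18 radial glia members and 13 of the 14 neuron members, without Tubb3. Tubb3 was the highest neuron member. Without it the middle member by exon length is Map2, at 157.8 TPM, against a list median of 158 TPM. The genes missing from that scale thus account for little of the fall. Neurons, or their RNA, in the isolated fraction stay open as a source, as do transcripts held by the radial glia themselves: 28 of the 28 neuron, deep-layer and upper-layer genes were above 1 TPM, led by Tubb3 (6691 TPM) and Neurod6 (1791 TPM), which either would give; 0 of them are in another list. The labels do not say whether a gate on the Tubb-GFP reporter excluded such cells. No biological explanation was tested, since the design has a single group.

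Hopx, the gene named in the series title, had 176 counts over the 4 libraries. Loss of reads to the antisense gene Hopxos stays open: with all its counts placed on the bases it shares with no other gene, Hopx would be at 4.16 TPM against a radial glia median of 31.0 TPM, but this assumes even coverage, which was not measured. Hopxos itself had 17 counts, which does not count reads a counter drops as shared. By raw count, Hopx was at percentile 37.7 of tested genes, against medians of 83.7 for the radial glia list and 67.1 for the basal radial glia list; this cannot test the gene span behind the deposited TPM, which raw counts do not hold. Raw counts grow with transcript length, and by exon-length TPM these percentiles were 43.2, 79.8 and 56.6, with no biological explanation tested.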
